A study of Mus musculus with 9 samples.

How the data were processed

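Gene expression was measured by RNA-seq in 9 mouse ovary samples, 3 each of wild type, hyperplasia and granulosa cell tumour, as the labels group them. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a stranded TruSeq mRNA kit, which enriches polyadenylated RNA. The submitters' processing notes name FastQC, STAR 2.7.1a, Picard 2.8.1, RSEM 1.3.1 and the mouse genome build GRCm38, without saying which step each served. The strand setting used for counting is not given in the sources used here.

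For each sample the authors deposited a gene table of RSEM with expected counts, TPM and FPKM, together with gene length and effective length. Per the file headers and values, the deposited expected counts are not normalised, and 25.6% of the values above 0 are not whole, because RSEM shares reads that map to several genes. This sharing can split reads between close relatives, so genes of families with near copies are described as uncertain. The deposited TPM values are scaled by the authors for gene length and depth and served in 1 alternative, and the deposited FPKM values were not used in any test. All 9 files list the same 55536 genes by identifier, all of which were found in GENCODE M21 for GRCm38. Symbols and coordinates were taken from that annotation, whose release was inferred from the identifiers.

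Expected counts were rounded to whole numbers and summed per library. Totals ran from 11661876 (tumour library 3) to 20890536 (wild-type library 1), and mitochondrial genes took 2.54% to 4.18% of the counts. A floor of 3 counts corresponds to 0.144 to 0.293 CPM in single libraries, and over a group to 0.0551 CPM in wild type, 0.0562 in hyperplasia and 0.0805 in tumours. Genes with 0 counts in a whole group were given as a bound against the floor over that group, and those with 1 to 3 counts as a ratio with an exact 95% counting interval. Every pair of libraries was checked for duplication by a chi-square test over genes, and the smallest value per degree of freedom was 29.0, far above sampling noise, so each library was counted once.

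The main test was edgeR 4.0.16 (R 4.3.3) on the rounded counts. It used TMM scaling (factors 0.797 to 1.078), the filter filterByExpr with a count minimum of 10 and a total minimum of 15, which left 16213 genes, and the quasi-likelihood test with 1 fit over all 9 libraries and their 3 groups. Contrasts were tumour against wild type, hyperplasia against wild type, tumour against hyperplasia, and the mean of both lesion groups against wild type. P-values were adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. The common biological coefficient of variation was 0.43, and the median standard error of a log2 fold change was 0.38 (0.33 for all mutant samples).

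Gene lists were tested on the same contrasts with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over 26 lists per comparison, then with an estimated correlation and with fry. The lists cover granulosa cell identity, Sertoli cell and testis determination, steroid hormone synthesis, theca cell, luteal cell, ovulation and cumulus expansion, hormone and growth factor receptors, oocyte, cell cycle, TGF-beta, activin and BMP signalling, Wnt signalling, Hippo-YAP targets, Notch signalling, MAPK feedback, p53 targets, hypoxia, interferon response, extracellular matrix and stromal fibroblast, smooth muscle, endothelium, macrophage, lymphocyte, ovarian surface epithelium, oviduct, adipocyte and red blood cell. With the preset correlation 9, 4, 10 and 7 lists were called in the 4 comparisons in the order above. None of these calls held with an estimated correlation (camera, smallest adjusted p 0.135, 0.145, 0.0792 and 0.069), and fry, which tests whether a list moves on balance without comparing it with other genes, called 7, 0, 6 and 2. For tumour against wild type these were the oocyte, adipocyte, luteal, ovulation, macrophage, endothelium and TGF-beta lists. For tumour against hyperplasia they were the luteal, ovulation, smooth muscle, macrophage, lymphocyte and adipocyte lists, and for all mutant samples the oocyte and adipocyte lists.

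The groups, contrasts, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule names Foxl2 and, among called genes with a mean of at least 1 CPM, non-overlapping groups and a symbol that is not a predicted locus, a clone or an antigen receptor segment, the 8 highest and 8 lowest fold changes, or 5 per direction for the last 2 comparisons. It also takes up to 4 members of each list, those with the smallest adjusted p. Cdh13, Eya4 and Opcml, which the rule does not name for hyperplasia against wild type, were carried over to it from the other comparisons after their values were seen.

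The alternatives chosen at that time were the size factors of DESeq2, the DESeq2 1.42.0 Wald test, limma-voom, no low-count filter, limma on log2(TPM + 1), a fit of only the groups compared, a model term for the 2 libraries with a shared title stem, and each library left out in turn. After the data were seen, 3 were added: leaving out wild-type library 1 and tumour library 2, an offset for a trend on gene length fitted per library (lowess span 0.4), and limma-voom with sample weights. The procedure was tested on simulated counts with 200 changed genes in each of 5 simulations per comparison. No simulated library stood apart from its group, so the recovered shares may be too high for the real data. For tumour against wild type, changes of 2-, 4-, 16- and 64-fold were recovered at 4.4%, 51.2%, 92.8% and 97.2%, with 4.4% false calls, over 15953 genes. For tumour against hyperplasia the recovered shares were 4.8%, 48%, 88.8% and 98.8%, with 4.6% false calls, over 15951 genes. Correlations between libraries used log2(CPM + 1) of 14544 genes with a mean count of at least 20. Tables were handled with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and plots were drawn with matplotlib 3.10.9. The filter was rerun in each fit, which left 16522 to 16703 genes with libraries left out and 15236 to 16015 with only the groups compared. List medians from those fits can therefore cover other members than the main fit. Genes below the main filter entered some of these fits, the fit without a filter, the library totals and the counts given for Dmrt1.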

Results

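RNA-seq was used to profile ovaries of mice with a mutated copy of Foxl2, a forkhead transcription factor that maintains granulosa cells, the somatic cells that surround the oocyte. The 9 samples fell into 3 groups of 3. Wild-type ovaries carried unmutated Foxl2 (FOXL2 WT/WT), and the other 6 samples were heterozygous for the C134W change (FOXL2 WT/C134W), of which 3 were labelled as hyperplasia and 3 as granulosa cell tumour. The series asks which genes are dysregulated in mouse adult-type granulosa cell tumours relative to normal ovaries. Wild-type libraries 1, 2 and 3 held 20890536, 15778631 and 16342143 counts on genes, the hyperplasia libraries 18202064, 13353551 and 19961739, and the tumour libraries 15163347, 12886802 and 11661876. Levels are given in CPM (counts-per-million units, scaled by the trimmed mean of M-values, TMM), as mean ± SD over 3 libraries. The labels do not say that the samples came from separate animals, and hyperplasia library 3 and tumour library 3 share a title stem, so p-values measure only the spread between these samples. In the 3 tumours, 3 counts over the group corresponded to 0.0805 CPM, the floor used for genes with 0 counts there. All intervals and floors cover counting error only.

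Foxl2 (ENSMUSG00000050397, GRCm38 chromosome 9, 98955288 to 98958543, plus strand) was detected in all 9 libraries. Its level was 176 ± 28.6 CPM (SD, n = 3) in wild type, 217 ± 109 CPM in hyperplasia and 294 ± 83.7 CPM in tumours. All 3 tumours (268, 227 and 388 CPM) lay above all 3 wild-type ovaries (203, 146 and 178 CPM), but the log2 fold change of 0.74 (SE 0.37) did not pass the threshold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.298). Gene counts sum both alleles and cannot show the mutated base, so they do not check the genotype labels. The antisense gene Foxl2os overlaps the first 12 bases of Foxl2 in the annotation, and the strand setting of the counting is not stated, so a small part of the signal is uncertain.

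In tumours compared with normal ovaries, the oocyte, adipocyte, luteal and steroid synthesis lists fell, with 6 oocyte and 3 adipocyte genes at 0 counts, and a smaller set of genes rose, among them Opcml, Eya4, Oprl1 and Nell1. These list calls were made with a preset correlation between genes and were lost with an estimated correlation (camera, BH, smallest adjusted p = 0.135). Of 16213 genes tested, 259 passed the threshold, 57 higher and 202 lower in tumours, all with changes above 2-fold (edgeR quasi-likelihood test, hereafter edgeR QL, with Benjamini-Hochberg, BH, adjustment). Opcml (chromosome 9, 27790775 to 28925410), a cell adhesion molecule anchored to the membrane, rose from 0.315 ± 0.126 CPM in wild type to 37.3 ± 35.7 CPM in tumours (log2 fold change 6.86, SE 1.07, edgeR QL, BH adjusted p = 0.0356). Eya4 (chromosome 10, 23102963 to 23350786), a transcriptional coactivator and phosphatase, rose from 1.1 ± 0.794 to 52.5 ± 20.5 CPM (5.59, SE 0.79, edgeR QL, BH adjusted p = 0.03). Oprl1, the nociceptin receptor (5.55, SE 1.11), Nell1, a secreted protein with EGF-like domains (5.52, SE 1.09), Aldh3a1, an aldehyde dehydrogenase (3.82, SE 0.77), Mapk10, the JNK3 kinase (3.58, SE 0.53), and Lrrc4, a leucine-rich repeat protein of synapses (3.53, SE 0.70), also rose, with edgeR QL, BH adjusted p between 0.0321 and 0.0473. The rise of Nell1 was from 3.58 ± 0.979 to 165 ± 108 CPM and that of Mapk10 from 9.33 ± 3.43 to 112 ± 46.5 CPM. The olfactory receptor gene Olfr316 rose too (3.71, SE 0.73, edgeR QL, BH adjusted p = 0.0464); it belongs to a large gene family, so reads shared with relatives make its value uncertain. These 8 are the highest only among genes kept by the naming rule, which leaves out predicted loci and clones, some of them called with higher fitted values.

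The oocyte list had the lowest median of the 26 lists tested in this comparison. All 18 measured members of the oocyte list were lower in tumours, with a median log2 fold change of −7.39, or −6.82 with the 6 members that had 0 counts in all tumours set at their bound. Of the 18 members, 8 fell by the adjustment over all genes and 16 fell when adjusted over the list alone (edgeR QL, BH). The list fell against other genes with a preset correlation (camera, BH adjusted p = 2.38e-23), and this call was lost at adjusted p = 0.135 with an estimated correlation. Zp2 (chromosome 7, 120126772 to 120145291), a protein of the egg coat, stood at 32.8 ± 3.28 CPM in wild type and had 0 counts in the 3 tumours, which makes it at least 407-fold lower against a floor of 3 counts over the group (edgeR QL, BH adjusted p = 0.0464). On the same floor Zar1, an oocyte RNA-binding protein, was at least 185-fold lower, Lhx8, a transcription factor of early oocytes, at least 21.1-fold lower, and Bcl2l10, an oocyte member of the Bcl2 family, at least 195-fold lower (edgeR QL, BH adjusted p between 0.0404 and 0.0452). Nlrp14, a maternal NLR family gene, had 1 count over the 3 tumours, a ratio of 1970 (95% counting interval 353 to 77700, edgeR QL, BH adjusted p = 0.0356). Dppa3, a maternal chromatin factor, had 2 counts and a ratio of 200 (55.0 to 1650), and Npm2, an oocyte nucleoplasmin, had 3 counts and a ratio of 123 (41.7 to 597). Zp1, another egg coat protein, fell by 6.68 on the log2 scale (SE 1.19, edgeR QL, BH adjusted p = 0.0404). Khdc1b, Trim61 and Obox2, which belong to families with closely related copies and are therefore uncertain, also had 0 counts in the tumours, at least 255-fold, 154-fold and 139-fold below wild type (edgeR QL, BH adjusted p between 0.0403 and 0.0473).

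Adipocyte genes followed the same direction. All 7 measured members of that list were lower in tumours, with a median of −6.70, or −5.72 with the 3 members at 0 counts set at their bound. Only 1 member, Cfd, the complement protease adipsin, fell by the adjustment over all genes, and 6 fell when adjusted over the list alone (edgeR QL, BH). Cfd stood at 16.3 ± 9.63 CPM in wild type and had 0 counts in tumours, at least 202-fold lower (edgeR QL, BH adjusted p = 0.0403), and on the same floor the adipokine genes Adipoq and Retn were at least 72.3-fold and 52.6-fold lower. The list fell (camera, BH adjusted p = 7.92e-08). Adipocyte genes lost this call at adjusted p = 0.135 with an estimated correlation (camera, BH).

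Luteal genes fell as a group, with 10 of 10 members lower and a median of −3.26 (camera, BH adjusted p = 1.19e-08). Luteal genes lost this call at adjusted p = 0.135 with an estimated correlation (camera, BH). Of the 10 members, 3 fell by the adjustment over all genes and 8 when adjusted over the list alone (edgeR QL, BH). Ptgfr (chromosome 3, 151796502 to 151837630), the receptor for prostaglandin F2α, dropped from 540 ± 457 to 5.17 ± 0.932 CPM (−6.71, SE 0.88, edgeR QL, BH adjusted p = 0.0287). Cyp11a1, which makes pregnenolone from cholesterol, dropped from 6785 ± 2419 to 714 ± 298 CPM (−3.25, SE 0.56), and Prlr, the prolactin receptor, from 659 ± 350 to 68.4 ± 48.5 CPM (−3.27, SE 0.64, edgeR QL, BH adjusted p = 0.0403 and 0.0464). Wild-type library 1, which stood apart from its group, had the highest luteal list mean (2.15 relative to the 9 libraries, with −0.21 and 1.10 in wild-type libraries 2 and 3). Sfrp4, a secreted Wnt antagonist, differed by −5.28 without passing (edgeR QL, BH adjusted p = 0.0556). The steroid hormone synthesis list shares Cyp11a1, Star, Hsd17b7 and Scarb1 with the luteal list. It fell with 11 of 15 members lower, a median of −1.54 and 1 member called over all genes (camera, BH adjusted p = 5.06e-04). Steroid synthesis genes lost this call at adjusted p = 0.26 with an estimated correlation (camera, BH). Adjusted over the list alone, 8 of its members fell and 1 rose (edgeR QL, BH). Its members Star, which carries cholesterol into mitochondria (−1.93), and Srd5a1, a 5α-reductase (−1.85), stood at edgeR QL, BH adjusted p = 0.0647 and 0.061. Genes of ovulation and cumulus expansion fell with 7 of 8 lower and a median of −1.98 (camera, BH adjusted p = 0.00339). Ovulation genes lost this call at adjusted p = 0.135 with an estimated correlation (camera, BH). By edgeR QL 0 of them passed over all genes and 4 fell when adjusted over the list alone. Runx2, a transcription factor induced at ovulation, stood at −3.81 and Ptgs2, the cyclooxygenase of ovulation, at −3.34.

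Genes of blood-derived and vascular cells were also lower. The macrophage list fell with 11 of 12 members lower and a median of −1.21, and the test gave a decrease (camera, BH adjusted p = 8.71e-07). Macrophage genes lost this call at adjusted p = 0.163 with an estimated correlation (camera, BH). By edgeR QL, 1 member fell by the adjustment over all genes and 10 when adjusted over the list alone. That member was Itgam, an integrin of myeloid cells, which dropped from 17 ± 3.34 to 5.43 ± 0.654 CPM (−1.65, SE 0.31, edgeR QL, BH adjusted p = 0.0451), while Cd68 (−2.04) and Mrc1 (−1.75) did not pass. The endothelium list fell with 11 of 12 lower and a median of −0.76 (camera, BH adjusted p = 5.06e-04). Endothelium genes lost this call at adjusted p = 0.227 with an estimated correlation (camera, BH). By edgeR QL 0 of its members passed over all genes and 5 fell when adjusted over the list alone, with the angiopoietin receptor gene Tek at −1.37 and Tie1 at −1.11. The smooth muscle list fell with 8 of 8 lower and a median of −1.75, which was −2.67 without tumour library 3 (camera, BH adjusted p = 3.95e-05). Smooth muscle genes lost this call at adjusted p = 0.306 with an estimated correlation (camera, BH). By edgeR QL 0 passed over all genes and 6 fell when adjusted over the list alone, with Lmod1 at −1.55 and Acta2 at −1.34. Lymphocyte genes were lower for 9 of 9 members, with 0 past the threshold by edgeR QL over all genes or adjusted over the list alone, with a median of −1.09, but the list was not called (camera, BH adjusted p = 0.056).

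The granulosa cell identity list was not called. Its median was 0.52 (camera, BH adjusted p = 0.42), and Esr2, oestrogen receptor beta, was its only member past the threshold when adjusted over the list alone (edgeR QL, BH adjusted p = 0.0233). Over all genes Esr2 did not pass (edgeR QL, BH adjusted p = 0.0574), at 57.6 ± 21.2 CPM in wild type and 192 ± 35.1 CPM in tumours. Amh, the anti-Müllerian hormone of small growing follicles, stood at 218 ± 6.34 CPM in wild type and 15.8 ± 20.8 CPM in tumours (−3.79, SE 1.17). Amhr2, its receptor, stood at a log2 difference of 1.59 and Inhba, an activin subunit, at −3.14, and none of these 3 passed (edgeR QL, BH adjusted p between 0.119 and 0.196). The list of Sertoli cell and testis genes had a median of 0.11, with Sox9 at 1.80, and the theca cell list a median of 0.35 and a mean of −0.10 (camera, BH adjusted p = 0.864 for both lists). The ovarian surface epithelium list had a median of 1.13 with 10 of 10 fitted values above 0, but it was not called (camera, BH adjusted p = 0.864). Its members split the tumours: Krt18 stood at 227, 0.78 and 108 CPM, Krt19 at 396, 0.0975 and 76.9 CPM, and Upk3b at 472, 0.0975 and 142 CPM in tumour libraries 1, 2 and 3. Against wild type these 3 genes had log2 fold changes of 2.13, 1.79 and 1.77 (edgeR QL, BH adjusted p between 0.366 and 0.533), and the directions of Krt19 and Upk3b turned in the fit to TPM and with limma-voom. The oviduct list had 3 measured members, a median of −0.17 (camera, BH adjusted p = 0.664) and Ovgp1 at 81.3 CPM in wild-type library 2, and the red blood cell list a median of −0.84 (camera, BH adjusted p = 0.42).

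The cell cycle list fell slightly, with 21 of 23 members lower and a median of −0.63 (camera, BH adjusted p = 0.00816). Cell cycle genes lost this call at adjusted p = 0.793 with an estimated correlation (camera, BH). Ccnb1, the mitotic cyclin B1, stood at −1.44 and Kif11, a spindle motor, at −1.06, and 0 members passed by edgeR QL over all genes or adjusted over the list alone. The call was lost without tumour library 1 (median −0.33, camera, BH adjusted p = 0.15) and without tumour library 3 (−0.36, 0.135; range over alternatives 1.07e-08 to 0.793), and the median was −1.27 without tumour library 2. With a model term for the shared title stem the median was −0.34 and the call was also lost (camera, BH adjusted p = 0.116). Among signalling lists none was called by camera, while fry called TGF-beta, activin and BMP signalling lower (fry, BH adjusted p = 0.0367). TGF-beta, activin and BMP signalling had a median of −0.39 (camera, BH adjusted p = 0.0844) although its member Id2, an inhibitor of DNA binding, fell by 2.29 on the log2 scale (SE 0.42, edgeR QL, BH adjusted p = 0.0443). Hippo-YAP targets stood at 0.46 (0.0844), hormone and growth factor receptors at −0.17 (0.443), Wnt signalling at −0.09 (0.678), Notch signalling at −0.37 (0.42), MAPK feedback at 0.12 (0.864) and p53 targets at −0.01 (0.864), each with its camera, BH adjusted p. Hypoxia (−0.33) and interferon response (−0.29) both had camera, BH adjusted p = 0.42. Genes of extracellular matrix and stromal fibroblasts had a median of 0.25 and a mean of −0.21 (camera, BH adjusted p = 0.864), and their member Postn, a matrix protein, fell by 4.64 (SE 0.83, edgeR QL, BH adjusted p = 0.0404), from 79.3 ± 57.5 to 3.21 ± 2.19 CPM. For Wnt signalling and MAPK feedback the means were 0.12 and −0.15, opposite in sign to their medians. Adjusted over the list alone (edgeR QL, BH), 3 genes fell and 1 rose in the TGF-beta list, 2 fell and 1 rose among receptors, 1 rose among Hippo-YAP targets, and 1 fell in each of the Notch, hypoxia, matrix, theca and oviduct lists.

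**Figure D1:**
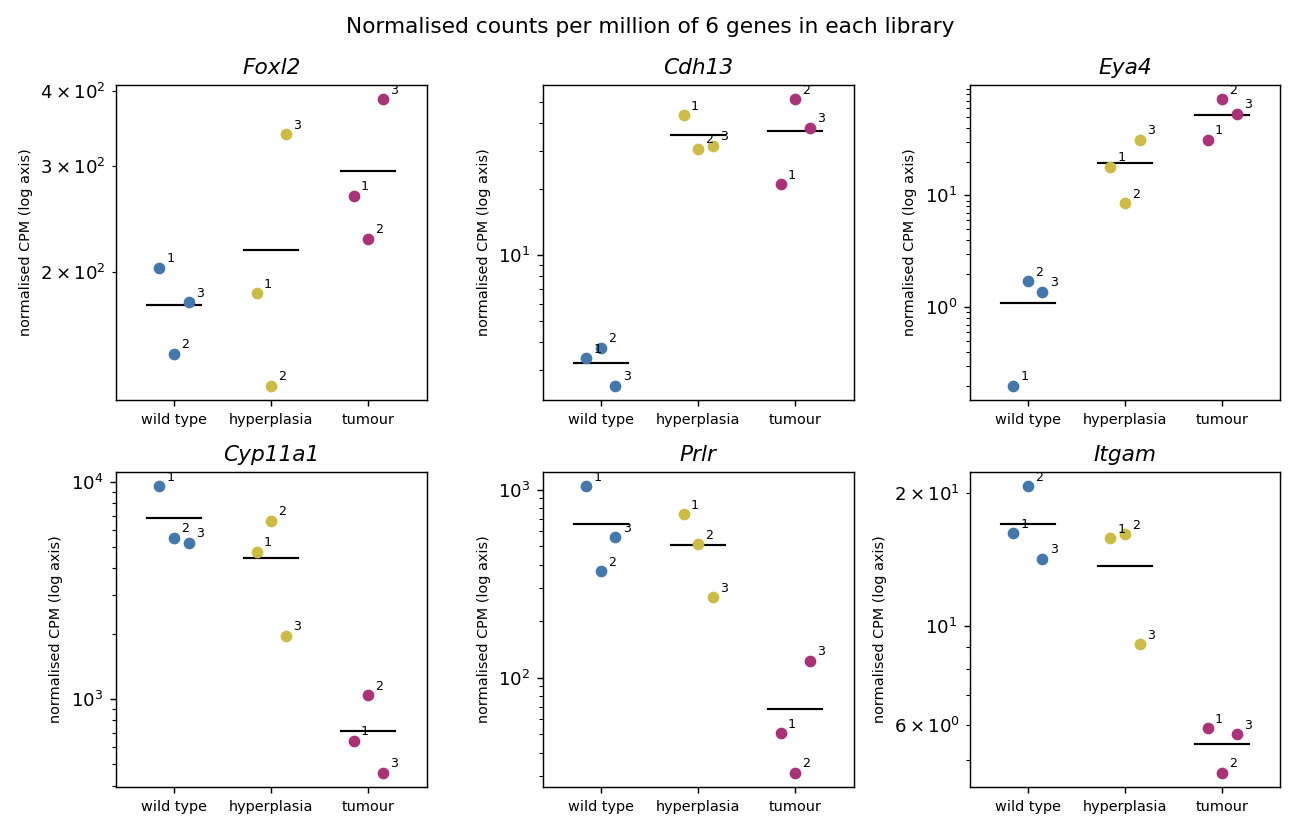
Normalised CPM on a log axis for Foxl2, Cdh13, Eya4, Cyp11a1, Prlr and Itgam, with 1 numbered point per library and a line at the mean of each group of 3. Cdh13 lies at 2.53 to 3.77 CPM in wild type and at 21.1 to 51.6 CPM in the 6 mutant libraries, while Cyp11a1 lies at 459 to 1042 CPM in tumours and at 5248 CPM or more in wild type.

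All 259 called genes had groups that did not overlap, as did 3906 genes (24.1%) of those tested, where chance gives 10%. At an unadjusted p under 0.05 there were 3262 genes (1364 higher, 1898 lower). The count rested on single libraries: without wild-type library 1, 2 or 3 the test called 15, 18 or 0 genes, and without tumour library 1, 2 or 3 it called 2, 69 or 0, with 2841 and 3146 genes at an unadjusted p under 0.05 (edgeR QL) in the fits that called 0. With a model term for the shared title stem it called 0 (edgeR QL, with 2610 at an unadjusted p under 0.05). Wild-type library 1 and tumour library 2 stood apart from their groups in the correlation across genes (r = 0.884 and 0.895 with the other wild types, and 0.871 and 0.883 with the other tumours). The deviation of each library from the mean of the other 8 was set against gene length across genes. For these 2 libraries rho was −0.63 and −0.31, and for the other 7 it lay between 0.08 and 0.42, so only wild-type library 1 exceeded the rest in size. The fit without both, an alternative chosen after the data were seen, called 8 genes.

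**Figure D2:**
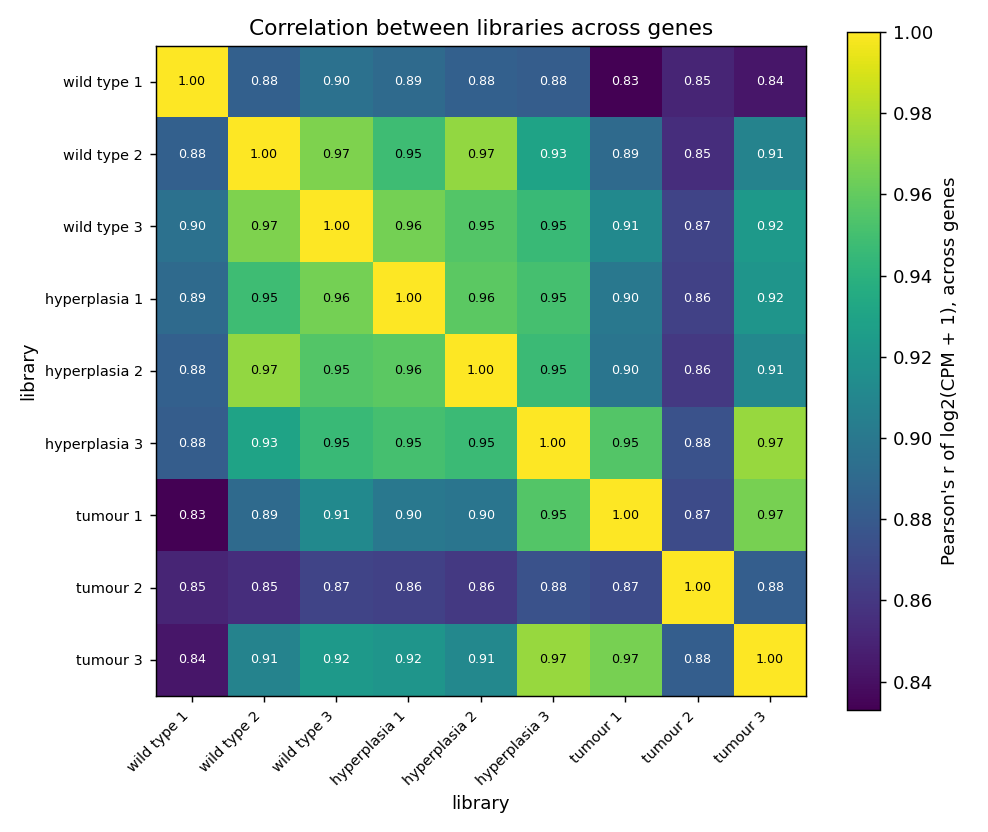
Pearson correlation across genes of log2(CPM + 1) between all pairs of the 9 libraries, shown as a heat map with the value in each cell (genes are not independent replicates). Wild-type libraries 2 and 3 correlate at 0.968 and tumour libraries 1 and 3 at 0.966, while hyperplasia library 3 correlates at 0.974 with tumour library 3 and at 0.951 and 0.947 with hyperplasia libraries 1 and 2.

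Hyperplastic ovaries were compared with wild type to describe the second lesion class of the mutant mice. Cdh13, a cadherin anchored to the membrane, was the gene nearest the threshold, at 3.23 ± 0.634 CPM in wild type and 35.3 ± 7.27 CPM in hyperplasia (log2 fold change 3.45, SE 0.37, edgeR QL, BH adjusted p = 0.091, range over alternatives 2.20e-14 to 0.626). Amh stood at 218 ± 6.34 CPM in wild type and 11.8 ± 4.9 CPM in hyperplasia (−4.21, SE 1.2, edgeR QL, BH adjusted p = 0.999). Eya4 (4.15) and Opcml (4.95), which rose in tumours, had differences of the same sign here without passing (edgeR QL, BH adjusted p = 0.956 and 0.999). For Foxl2 the difference was 0.31 (edgeR QL, BH adjusted p = 0.999), and −0.16 without hyperplasia library 3. As a list, oocyte genes fell, with 18 of 18 members lower and a median of −2.28 (camera, BH adjusted p = 9.77e-26). Oocyte genes lost this call at adjusted p = 0.145 with an estimated correlation (camera, BH). Among them Lhx8 stood at −2.96, Dppa3 at −2.74, Npm2 at −2.62 and Gdf9, an oocyte growth factor, at −2.27. The mean log2 level of the oocyte list relative to the 9 libraries was 1.69, −0.11 and −1.87 in hyperplasia libraries 1, 2 and 3, so these ovaries differed widely, and without library 1 the median was −3.91.

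Cell cycle genes fell as a list in hyperplasia, with 23 of 23 members lower and a median of −0.98 (camera, BH adjusted p = 1.73e-18). Cell cycle genes lost this call at adjusted p = 0.266 with an estimated correlation (camera, BH) and at 0.438 with fry (BH). Ovary samples mix cell types, and oocyte genes fell in the same libraries (median −2.28). In this and the other comparisons the cell cycle list is therefore not assigned to a cell type or read as proliferation of the lesion. Ccnb1 stood at 32.6 ± 3.12 CPM in wild type and 10.2 ± 4.39 CPM in hyperplasia (−1.68), Ccnb2 at −1.48, and the mitotic kinases Aurka and Plk1 at −1.27 and −1.25. Smooth muscle genes rose as a list, with 8 of 8 members higher and a median of 1.16 (camera, BH adjusted p = 3.09e-09). Smooth muscle genes lost this call at adjusted p = 0.266 with an estimated correlation (camera, BH). Lmod1, a leiomodin of actin filaments, stood at 37.7 ± 9.1 and 92.1 ± 28.4 CPM (1.29), smooth muscle actin, Acta2, at 665 ± 207 and 1414 ± 545 CPM (1.09), the myosin heavy chain gene Myh11 at 1.70 and the light chain gene Myl9 at 0.93. Adipocyte genes fell as a list, with 7 of 7 lower and a median of −2.27, which was −1.44 without wild-type library 1 and −3.47 without hyperplasia library 1 (camera, BH adjusted p = 4.82e-07). Adipocyte genes lost this call at adjusted p = 0.145 with an estimated correlation (camera, BH). Members included Cfd at −2.64 and Cidec, a lipid droplet protein, at −2.72. In these 4 lists 0 members passed by edgeR QL over all genes or adjusted over the list alone. Outside them the T cell coreceptor gene Cd4 was higher when adjusted over its list alone (3.03 ± 0.613 and 10.9 ± 3.82 CPM, 1.85, edgeR QL, BH adjusted p = 0.0132). The oviduct gene Ovgp1 was lower when adjusted over its list of 3 measured members alone (−4.99, edgeR QL, BH adjusted p = 0.0122), but not over all genes (0.999). That fold rested largely on the high level in wild-type library 2. The lowest wild-type level, 1.32 CPM, lay near the highest hyperplasia level, 1.09 CPM. Ptgs2 stood at 2.37.

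By edgeR QL with BH adjustment 0 of 16213 genes passed in hyperplasia against wild type, with 572 at an unadjusted p under 0.05, 0 calls by limma-voom and 19 by DESeq2. Groups did not overlap for 1591 genes (9.8%), where chance gives 10%. Simulated changes of 2-, 4- and 16-fold were recovered at 2.8%, 54.8% and 91.6% in this comparison. Most 2-fold changes were therefore not detectable with 3 libraries a group. The simulated data had 200 changed genes and no library that stood apart, which can raise these shares. Amh and Cdh13 differed by more than 4-fold here without passing, so 0 calls do not show that large changes were absent.

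**Figure D3:**
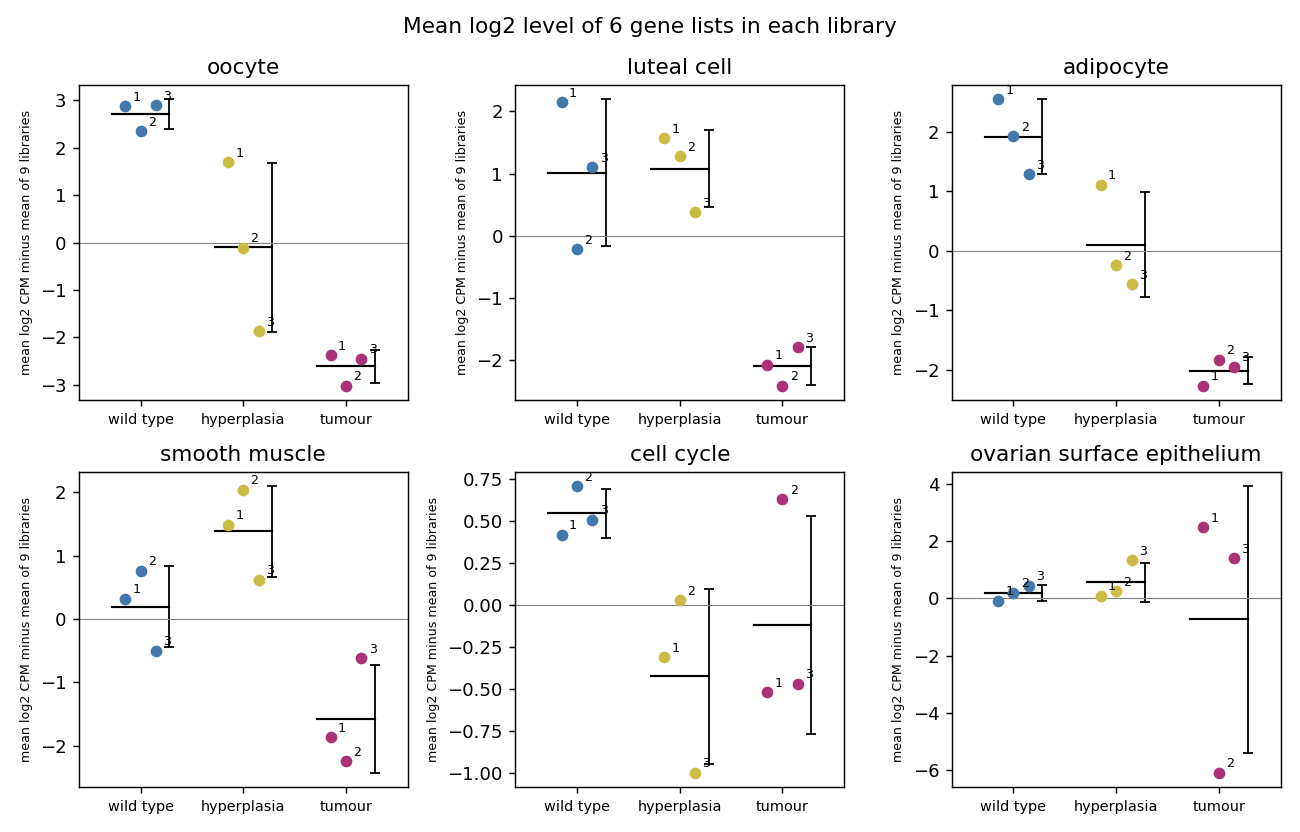
Mean log2 CPM of the members of 6 gene lists in each library, relative to the mean of the 9 libraries, with 1 numbered point per library, a line at the group mean and a bar of 1 SD. Smooth muscle lies at −0.50 to 0.76 in wild type, 0.62 to 2.04 in hyperplasia and −2.24 to −0.62 in tumours, and surface epithelium lies at −6.08 in tumour library 2 and at 2.47 and 1.39 in tumour libraries 1 and 3.

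Tumours were compared with hyperplasia to test whether the changes of the 2 lesion classes from wild type differed. All 30 genes that passed were lower in tumours (edgeR QL, BH), while DESeq2 called 119 higher and 697 lower, and without hyperplasia library 3 edgeR QL called 12 higher and 116 lower. With a model term for the shared title stem, which ties hyperplasia library 3 to tumour library 3, edgeR QL called 12 genes, 11 of them among the 30. Among the called genes, the largest change was in Gpnmb, a glycoprotein of macrophages and osteoclasts, from 358 ± 254 CPM in hyperplasia to 1.92 ± 1.06 CPM in tumours (−7.53, SE 0.72, edgeR QL, BH adjusted p = 0.011). Mmp12, the macrophage elastase, fell from 81.6 ± 52.2 to 0.492 ± 0.521 CPM (−7.46, SE 0.93), and Atp6v0d2, a proton pump subunit, from 42.5 ± 22 to 0.44 ± 0.281 CPM (−6.64, SE 0.61). Rergl, a Ras-like gene, had 1 count over the 3 tumours and a ratio of 103 (95% counting interval 18.1 to 4080), and Cyp2e1, a cytochrome P450, had 1 count and a ratio of 83.1 (14.6 to 3310). Mmp12, Rergl and Cyp2e1 passed with edgeR QL, BH adjusted p between 0.0363 and 0.0434, and Atp6v0d2 with 0.011. Foxl2 differed by 0.44 (edgeR QL, BH adjusted p = 0.633).

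Smooth muscle genes fell as a list from hyperplasia to tumour, with 8 of 8 members lower, a median of −3.15, 1 member called over all genes and 8 adjusted over the list alone (camera, BH adjusted p = 1.31e-16). Smooth muscle genes lost this call at adjusted p = 0.0961 with an estimated correlation (camera, BH). Lmod1 fell from 92.1 ± 28.4 to 12.9 ± 6.11 CPM (−2.84, SE 0.40, edgeR QL, BH adjusted p = 0.0363), and Acta2 (−2.42), Tagln (−3.07) and Actg2 (−3.35), which encode contractile proteins, stood at edgeR QL, BH adjusted p between 0.0659 and 0.0959. Luteal genes fell with 8 of 10 lower, a median of −2.76, 1 member called over all genes and 7 adjusted over the list alone (camera, BH adjusted p = 3.09e-10). Luteal genes lost this call at adjusted p = 0.0961 with an estimated correlation (camera, BH). Ptgfr fell from 297 ± 85.6 to 5.17 ± 0.932 CPM (−5.85, SE 0.84, edgeR QL, BH adjusted p = 0.0402), and Star (−2.26), Cyp11a1 (−2.64) and Prlr (−2.89) did not pass. The steroid hormone synthesis list fell with 9 of 15 lower and a median of −0.90 (camera, BH adjusted p = 0.0012). Steroid synthesis genes lost this call at adjusted p = 0.238 with an estimated correlation (camera, BH). Ovulation genes fell with 8 of 8 lower and a median of −1.78, which was −2.68 without tumour library 2 (camera, BH adjusted p = 1.95e-05). Ovulation genes lost this call at adjusted p = 0.0792 with an estimated correlation (camera, BH). Members included Ptgs2 at −5.71 and Tnfaip6, a hyaluronan-binding protein, at −4.05. In the steroid and ovulation lists 0 members passed over all genes by edgeR QL, and 4 in each fell when adjusted over the list alone.

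Oocyte genes fell further from hyperplasia to tumour, with 17 of 18 lower and a median of −4.74, or −4.43 with members at 0 counts set at their bound (camera, BH adjusted p = 2.72e-10). Oocyte genes lost this call at adjusted p = 0.238 with an estimated correlation (camera, BH). The median in the main fit, −4.74, became −3.09 without hyperplasia library 1. In a fit of the 6 samples compared the median was −1.51 and the call was lost (camera, BH adjusted p = 0.179, range over alternatives 6.05e-23 to 0.238). The filter was rerun in that fit without the wild-type libraries, so its median does not cover all 18 members. Lhx8, for example, had 11 counts over the hyperplasia libraries and 0 over the tumours, too few to pass. The value of −1.51 is therefore not directly comparable with −4.74. Adipocyte genes fell with 7 of 7 lower and a median of −3.98, or −3.23 at the bound, and −1.71 without hyperplasia library 1 (camera, BH adjusted p = 1.10e-04). Adipocyte genes lost this call at adjusted p = 0.19 with an estimated correlation (camera, BH). Macrophage genes fell with 11 of 12 lower and a median of −0.73, which was −1.31 without tumour library 2 (camera, BH adjusted p = 3.22e-06). Macrophage genes lost this call at adjusted p = 0.211 with an estimated correlation (camera, BH). Members included Cd68 at −2.37 and Itgam at −1.33. Lymphocyte genes fell with 9 of 9 lower and a median of −1.67 (camera, BH adjusted p = 3.02e-04). Lymphocyte genes lost this call at adjusted p = 0.238 with an estimated correlation (camera, BH). Members included Cd4 at −1.96 and Cd3e at −1.81. Endothelium genes fell with 11 of 12 lower and a median of −0.43, which was −0.65 without hyperplasia library 3, −0.79 without tumour library 2 and −0.28 without tumour library 3 (camera, BH adjusted p = 0.00196). Endothelium genes lost this call at adjusted p = 0.238 with an estimated correlation (camera, BH). Members included Tek at −1.27 and Vwf, von Willebrand factor, at −1.60. In these 5 lists 0 members passed over all genes by edgeR QL, while adjusted over the list alone 14 oocyte, 4 adipocyte, 4 macrophage, 5 lymphocyte and 2 endothelium genes fell. Among lists not called, adjusted over the list alone, 2 genes fell in the TGF-beta list, 1 in the matrix list, and 1 fell and 1 rose among receptors (edgeR QL, BH).

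The cell cycle list was higher in tumours than in hyperplasia for 20 of 23 members, with a median of 0.41 (camera, BH adjusted p = 0.0227). Cell cycle genes lost this call at adjusted p = 0.688 with an estimated correlation (camera, BH). Its replication licensing members Mcm7 and Mcm2 stood at 0.46 and 0.66. This call was not stable. In a fit of the 6 samples compared the median was 0.39 and the call was lost (camera, BH adjusted p = 0.0523). Without tumour library 2 the median was −0.23, without hyperplasia library 3 it was 0.16 and the call was lost (camera, BH adjusted p = 0.53, range over alternatives 4.06e-05 to 0.92), and without hyperplasia library 2 it was 0.65. With the 2 libraries that stood apart left out it was −0.25, and with sample weights −0.11. The count of 30 genes became 9, 3 or 128 without hyperplasia library 1, 2 or 3, and 2, 10 or 0 without tumour library 1, 2 or 3 (edgeR QL, with 2515 genes at an unadjusted p under 0.05 where it was 0). At an unadjusted p under 0.05 the whole set gave 2287 genes (764 higher, 1523 lower), and 3553 (21.9%) did not overlap between groups, where chance gives 10%. The fit without the 2 libraries that stood apart called 0 genes (edgeR QL, with 3081 at an unadjusted p under 0.05).

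When the 6 mutant samples were set against the 3 wild-type ovaries, 2 genes passed. Cdh13 (chromosome 8, 118283733 to 119324921) rose, from 3.23 ± 0.634 CPM in wild type to 35.3 ± 7.27 CPM in hyperplasia and 37 ± 15.3 CPM in tumours (log2 fold change 3.48, SE 0.35, edgeR QL, BH adjusted p = 0.0419, range over alternatives 6.69e-20 to 0.135). Mfap4 (chromosome 11, 61485431 to 61488900), a protein of elastic microfibrils, fell from 54.1 ± 4.18 CPM to 19.5 ± 4.33 and 9.64 ± 2.44 CPM (−1.98, SE 0.21, edgeR QL, BH adjusted p = 0.0419, range over alternatives 4.65e-12 to 0.135). Each was higher or lower, respectively, in 6 of 6 mutant libraries than in all 3 wild types. Amh, lower in the 6 mutant libraries as well, did not pass (−4.00, edgeR QL, BH adjusted p = 0.107), nor did Dppa3 (−5.08), Lhx8 (−5.37), Cfd (−6.84) or Foxl2 (0.53), with edgeR QL, BH adjusted p between 0.0715 and 0.576. Lhx8 and Cfd had 0 counts in all tumours, so their fitted values here depend on the prior count and are not measured folds.

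Among lists, oocyte genes fell with 18 of 18 members lower in the mutant samples and a median of −4.94 (camera, BH adjusted p = 3.68e-37). Oocyte genes lost this call at adjusted p = 0.069 with an estimated correlation (camera, BH). Adipocyte genes fell with 7 of 7 lower and a median of −4.71 (camera, BH adjusted p = 7.09e-11). Adipocyte genes lost this call at adjusted p = 0.069 with an estimated correlation (camera, BH). In the tumours 6 oocyte and 3 adipocyte members had 0 counts, so fitted values that depend on the prior count enter both medians. Cell cycle genes fell with 23 of 23 lower and a median of −0.81 (camera, BH adjusted p = 9.78e-08). Cell cycle genes lost this call at adjusted p = 0.393 with an estimated correlation (camera, BH). Luteal genes fell, with a median of −1.88 that was −1.03 without wild-type library 1 (camera, BH adjusted p = 2.11e-07). Luteal genes lost this call at adjusted p = 0.213 with an estimated correlation (camera, BH). Macrophage genes fell, with 11 of 12 lower and a median of −0.86 (camera, BH adjusted p = 4.58e-05). Macrophage genes lost this call at adjusted p = 0.366 with an estimated correlation (camera, BH). The steroid list (−0.80) and the endothelium list (−0.52) fell (camera, BH adjusted p = 0.00288 and 0.00336, and adjusted p = 0.366 for both with an estimated correlation). Without wild-type library 1 the steroid list stood at −0.30 and its call was lost (camera, BH adjusted p = 0.135, range over alternatives 2.49e-04 to 0.366). With a model term for the shared title stem the endothelium list stood at −0.40 and its call was lost (camera, BH adjusted p = 0.0591, range over alternatives 2.28e-04 to 0.366). By edgeR QL 0 members of these 7 lists passed over all genes, and 16 oocyte, 5 adipocyte, 5 luteal, 1 macrophage and 1 steroid gene fell when adjusted over the list alone. Among lists not called, Amh was lower when adjusted over the granulosa list or the Sertoli list alone (edgeR QL, BH adjusted p = 0.0311 and 0.0186). Adjusted in the same way, 2 genes fell and 1 rose among receptors, and 1 fell in each of the ovulation, Notch, matrix and oviduct lists.

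At an unadjusted p under 0.05 this comparison gave 1921 genes, and 701 (4.3%) did not overlap between groups, where chance gives 2.4%. Without wild-type library 1, 2 or 3 it called 0, 2 or 0 genes, without hyperplasia library 1, 2 or 3 it called 134, 0 or 1, and without tumour library 1, 2 or 3 it called 1, 7 or 0. With the stem term it called 0 (edgeR QL, with 1288 at an unadjusted p under 0.05). In the 4 fits without a library that gave 0 calls, edgeR QL gave 1541 to 1968 genes at an unadjusted p under 0.05. The tumour and hyperplasia comparisons had 0 called genes in common by edgeR QL, since hyperplasia had none, and 15 by DESeq2. Their fold changes correlated across genes at r = 0.60, where simulated unchanged groups against the same wild-type libraries gave 0.50, and with a covariance of 0.54 against a simulated 0.17 (SD 0.0053 over 20 simulations), a difference of 0.37. The same sign was seen for 66.5% of genes, against 66.7% in the simulation. Part of any excess in the correlation or the overlap may come from the shared controls, since 3 wild-type libraries cannot be divided into parts of at least 2 each. The difference in covariance takes the part of the shared controls away only as far as the simulation reproduces it. The simulation has no outlying wild-type library, while wild-type library 1 stood apart, so the real part may be larger. It also treats the lesion libraries as independent, so this difference is not taken as a shared effect. Hyperplasia library 3 and tumour library 3 share a title stem. Those 2 libraries correlate at 0.974, and wild-type library 2 and hyperplasia library 2 at 0.973, so the correlation itself does not show dependence.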

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

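The tests of oviduct tissue, gene length and tumour cell share below were chosen only after the results were seen, while the contrast of tumour against hyperplasia and the counts of other splits were planned.

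The results listed here differed between the 2 lesion classes, by the test of the difference itself, since tumour against hyperplasia compares their changes from wild type. The 30 genes called, all lower in tumours, included Gpnmb (−7.53), Mmp12 (−7.46), Atp6v0d2 (−6.64), Ptgfr (−5.85) and Lmod1 (−2.84), and Rergl and Cyp2e1, with 1 count each over the 3 tumours, whose fitted values of −6.28 and −6.05 depend on the prior count (edgeR QL). Among lists, the medians were −3.15 for smooth muscle, −2.76 for luteal cells, −4.74 for oocytes, −3.98 for adipocytes, −1.78 for ovulation, −0.90 for steroid hormone synthesis, −0.73 for macrophages, −1.67 for lymphocytes, −0.43 for endothelium and 0.41 for the cell cycle. With members at 0 counts set at their bound, the oocyte and adipocyte medians were −4.43 and −3.23. None of these list calls held with an estimated correlation (camera, smallest adjusted p 0.0792). Without hyperplasia library 1 the oocyte and adipocyte medians were −3.09 and −1.71, and without tumour library 2 those of ovulation, macrophages and endothelium were −2.68, −1.31 and −0.79. Endothelium stood at −0.65 without hyperplasia library 3 and −0.28 without tumour library 3. The cell cycle median was −0.23 without tumour library 2, 0.65 without hyperplasia library 2 and 0.16 without hyperplasia library 3, where its call was lost. With a model term for the shared title stem the count of 30 genes became 12 (edgeR QL). It became 9, 3 or 128 without hyperplasia library 1, 2 or 3, and 2, 10 or 0 without tumour library 1, 2 or 3 (edgeR QL, with 2515 at an unadjusted p under 0.05 where it was 0).

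With 3 samples a group, other splits are too few for a share under 0.05, since 10 splits cannot go below 0.1. For tumour against wild type 1 of the 10 splits, the real one, gave as many genes (259, highest other 0). For tumour against hyperplasia 1 of 10 did (30, highest other 4). For hyperplasia against wild type the real count was 0, so 10 of 10 gave as many by construction, which tests nothing. For all mutant samples against wild type, a model of 2 groups called 1 gene, and 8 of the 84 splits of the 9 samples gave as many, so chance cannot be excluded for that count. The highest other split, the 3 tumours against the rest, called 271 genes, and hyperplasia library 3 with tumour libraries 1 and 3 against the rest called 112. The first of these splits is the tumour label itself, and only the second departs from the labels.

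Smooth muscle genes were higher as a list in hyperplasia than in wild type and lower in tumours, calls lost at adjusted p = 0.266 and 0.306 with an estimated correlation (camera, BH). The libraries overlapped, with a list mean of 0.62 in hyperplasia library 3 and 0.76 in wild-type library 2. For this pattern 3 technical explanations were weighed. Oviduct dissected with the hyperplasia samples was tested by Ovgp1, an abundant oviduct transcript. Its highest hyperplasia level, 1.09 CPM, lay just below the lowest wild-type level of 1.32 CPM, so it gave no sign of more oviduct. The oviduct list means overlapped, at 0.13 in hyperplasia library 3 and 0.04 in wild-type library 3. With 1 gene and so small a gap the test cannot decide. A gene length trend between libraries is argued against, because the tumour against hyperplasia median was −3.11 with the trend removed and −3.15 before (camera, BH adjusted p = 8.04e-16 and 1.31e-16, range over alternatives 8.02e-21 to 0.0961). A larger share of tumour cells that lowers every other cell type alike was tested against endothelium alone. From hyperplasia to tumour the smooth muscle median minus the endothelium median was −2.72, with SDs over members of 0.8 and 0.51. That gap includes the smooth muscle rise in hyperplasia (median 1.16), and against wild type the tumour medians were −1.75 and −0.76. From hyperplasia to tumour the luteal median (−2.76) lay near that of smooth muscle, while lymphocytes (−1.67) and macrophages (−0.73) fell less. SDs over members do not measure the spread between samples, so the test cannot decide. Smooth muscle of the oviduct, uterus, ligament or vessel walls in the dissected tissue and a change in the ovarian stroma both stay open. Either may differ between lesion classes for biological or dissection reasons.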

How the results depend on the processing

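The fits without wild-type library 1 and tumour library 2, with the length offset and with sample weights were chosen only after the data were seen. Of 42 calls of genes named by the rule or in the text and 30 called lists, over 21 settings 0 genes and 1 list changed direction, but of these 42 calls 20 were lost by limma-voom, 40 with the title stem term, 41 without the 2 libraries and all 42 without tumour library 3. In tumour against wild type (main count 259) 1747 genes were called by the DESeq2 Wald test, 721 with no low-count filter, 428 on TPM, 418 with the length offset, 1318 with sample weights, 8 without the 2 libraries and 0 with the title stem term (edgeR QL, 2610 at an unadjusted p under 0.05), and 0 to 69 with each library left out. DESeq2's calls held all 259, limma-voom's 176 and those without tumour library 2 39 of them. For hyperplasia against wild type (0 by edgeR QL, 572 at an unadjusted p under 0.05) these counts were 19 by DESeq2, 2 with no filter, 1 on TPM, 3 with weights, 2 without the 2 libraries and 3 with only the groups compared, and 0 in every fit with a library left out. For tumour against hyperplasia (30) they were 816 by DESeq2, 199 with no filter, 76 on TPM, 4 by limma-voom, 93 with the length offset, 91 with weights, 12 with the stem term, 1 with only the groups compared, 0 without the 2 libraries (3081 at an unadjusted p under 0.05), and 0 to 128 with a library left out. For all mutant samples (2) they were 591 by DESeq2, 331 with no filter, 173 on TPM, 198 by limma-voom, 639 with weights, 0 with the length offset or the stem term (2258 and 1288 at an unadjusted p under 0.05), and 0 to 134 with a library left out. The overlap of both comparisons against wild type (0) was 15 by DESeq2 (independent lists give 0.41 up and 0.56 down, which leaves out the shared wild-type libraries, so no excess is claimed), 1 with no filter and 3 with weights. The size factors of DESeq2 moved no count by over 1.5 times.

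Directions turned as follows, with medians for lists, whose direction is that of the test. In tumour against wild type, limma-voom gave −1.11 for Upk3b, −1.03 for Krt19 and −1.04 for surface epithelium, and TPM gave −0.13 for Upk3b, −0.54 for Krt19, −0.26 for Wnt and 0.06 for matrix. DESeq2 gave −0.10 for Wnt, the fit without the 2 libraries −0.02 for Wnt, weights 0.40 for oviduct, and fry 0.11 for Sertoli and 0.35 for theca. The stem term gave 0.80 for surface epithelium, −0.27 for Sertoli, 0.14 for theca, 0.05 for p53 and, in hyperplasia against wild type, −0.09 for Foxl2. For the cell cycle in tumour against hyperplasia, the fit without the 2 libraries gave −0.25 and weights −0.11. With each library left out in turn, tumour against wild type ranged from −0.24 to 2.37 for Krt19, 0.15 to 1.71 for surface epithelium, −0.41 to 0.28 for Wnt, −0.16 to 0.47 for matrix, −0.22 to 0.53 for Sertoli, −0.20 to 0.44 for theca, −0.40 to 0.14 for p53, −0.40 to 0.08 for receptors and −2.95 to 0.61 for red blood cell. Foxl2 in hyperplasia ranged from −0.16 to 0.58 and the cell cycle in tumour against hyperplasia from −0.23 (without tumour library 2) to 0.65. The cause was not tested. On TPM the median of all genes was −0.119, 0.132 and −0.226 in the first 3 comparisons (0.011, −0.003 and 0.05 in the main fit), so those values are relative to it. At these depths and 3 libraries a group, most 2-fold changes are out of reach, and genes near the floor have no measurable fold. No paired analysis was possible because the replicate numbers follow accession order and the title stems give only 1 possible pair, which was fitted as the stem term above.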

Other observations

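The genes and lists in this part, and the tests of tumour library 2, hyperplasia library 3 and Amh, were chosen only after the results were seen.

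The genes called lower in tumours than in wild-type ovaries included Lgals3, Ptprc and Itgax, which are in none of the fixed lists. Lgals3, which encodes galectin-3, fell from 93.1 ± 9.1 to 4.94 ± 2.44 CPM (SD, n = 3 each; log2 fold change −4.25, SE 0.40, edgeR QL, BH adjusted p = 0.0185). Ptprc, the CD45 antigen of leukocytes, fell from 21.3 ± 2.69 to 6.8 ± 0.36 CPM (−1.65), and Itgax, the CD11c integrin of dendritic cells and macrophages, from 11.5 ± 3.89 to 1.91 ± 0.728 CPM (−2.59, edgeR QL, BH adjusted p = 0.0356 and 0.0403). The called genes also held 3 that encode mast cell proteases, a class for which no list was tested. Cma1 fell from 8.63 ± 6.59 to 0.145 ± 0.173 CPM (−5.89) and Tpsb2 from 10 ± 7.35 to 0.339 ± 0.367 CPM (−4.88), while Mcpt4 had 2 counts over the 3 tumours, a ratio of 56.1 (95% counting interval 15.3 to 467). All 3 passed with edgeR QL, BH adjusted p between 0.0404 and 0.0497. In wild type these 3 genes varied widely, with Cma1 at 14.9, 9.19 and 1.78 CPM. Like the other called genes, the 6 genes of this paragraph lost their calls without wild-type library 3 or tumour library 3, where 0 genes passed (edgeR QL, with 2841 and 3146 genes at an unadjusted p under 0.05).

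The tumours differed among themselves. Genes of the ovarian surface epithelium were abundant in tumour libraries 1 and 3 and near the floor in tumour library 2. Fshr, the receptor for follicle-stimulating hormone, stood at 81.8 and 80.7 CPM in tumour libraries 1 and 3 and had 0 counts in tumour library 2, which allows up to 0.293 CPM. Wt1, a transcription factor of granulosa cells and surface epithelium, stood at 422, 2.54 and 205 CPM in tumour libraries 1, 2 and 3, and Inhbb, an activin and inhibin subunit, at 48.3, 1070 and 154 CPM, while Foxl2 stood at 268, 227 and 388 CPM. Among Sertoli cell genes, Cst9 had 123 counts in hyperplasia library 3, 80 in tumour library 1 and 75 in tumour library 3, and at most 3 in each other library. Dmrt1, a testis determination factor, had 23, 20 and 2 counts in the same libraries and 0 elsewhere, too few to be tested. The Sertoli list as a whole did not set these libraries apart. Its mean relative to the 9 libraries was 0.64, 0.67 and 0.71 in them, and 0.62, −0.43 and 0.49 in wild-type libraries 1, 2 and 3.

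For the low surface epithelium transcripts in tumour library 2, a gene length trend is argued against, since the list mean there was −6.08 with the trend removed, while the other 8 libraries lay between −0.23 and 2.48. Surface epithelium missing from that sample alone was also weighed. Of 20 granulosa list members, 4 (Amh, Emx2, Fshr and Wt1) lay more than 10 times below the lower of the other tumours. Wt1 and Emx2 are expressed in surface epithelium too, which leaves Amh and Fshr as members of the granulosa lineage. That is fewer members than the test asked for, so the test cannot decide. A tumour of a different cell state may account for the low surface epithelium and granulosa genes. But 1 library gives no test of this, and no biological explanation was tested.

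Hyperplasia library 3 lay nearer the tumours than the other hyperplasia libraries. On an axis across genes from the wild-type mean (0) to tumour library 1 (1), it stood at 0.52, against 0.15 and 0.19 for hyperplasia libraries 1 and 2, and tumour libraries 2 and 3 stood at 0.52 and 0.76. This axis does not use tumour library 3, but that library itself lay well along it. Whatever hyperplasia library 3 shares with tumour library 3, as their common title stem might bring, could therefore also move it along the axis. So the position cannot decide on a background shared with tumour library 3 alone. A tumour of the same makeup as the other 3 that carries a hyperplasia label is argued against, for luteal genes, by its luteal list mean of 0.38, where the tumours lay between −2.41 and −1.79. Other lists divided. Its ovulation list mean of 0.60 also lay apart from the tumours (−1.85 to −1.07). But its oocyte list mean of −1.87 lay nearer the tumours (−3.02 to −2.37) than hyperplasia libraries 1 and 2 (1.69 and −0.11). Tissue that holds both hyperplasia and tumour, a lesion between these classes, or an effect of a tumour elsewhere in the same animal may each account for it and stay open.

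Amh was lower in all 6 mutant libraries than in wild type, and a hypothesis was that it followed the loss of growing follicles in proportion to oocyte transcripts. In the hyperplasia libraries the Amh change minus the mean oocyte list change was −3.11, −2.20 and 0.85, with a mean of −1.49 and an SD of 2.07, and in the tumours it was 0.30, −4.21 and 2.7. Amh did not follow the oocyte list library by library, at −4.13, −5.02 and −3.73 in hyperplasia beside −1.02, −2.82 and −4.58. Taking the oocyte change away raised the SD of the Amh change in hyperplasia from 0.66 to 2.07, so the test lends the hypothesis no support, and 3 libraries that spread this widely do not exclude it.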
